A study of Homo sapiens with 16 samples.

How the data were processed

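RNA was measured in 16 libraries of the human promyelocytic leukaemia line HL-60, 12 from differentiated cells (dHL-60) in 6 groups of 2 and 4 from undifferentiated cells (uHL-60) in 4 groups of 1. Groups and replicate numbers were taken from the sample titles. The differentiation agent is not given in the sources used here. Per the labels, total RNA was made into sequencing libraries with a stranded mRNA kit. The deposited table holds counts, whole numbers of reads per gene and library with no normalization. The submitters' processing notes name fastp 0.20.0, HISAT2 2.1.0, featureCounts 2.0.1 from Subread, DESeq2 1.28.0, edgeR 3.36.0 and genome build GRCh38, with no role or order. The strand setting of the counting is not given in the sources used here, so antisense genes and genes that overlap others are uncertain, as are genes with near-identical copies.

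The deposited count table lists 23575 gene symbols, of which 23283 matched the RefSeq table and 23138 the Ensembl table used for names, 5600 have 0 counts in every library and 0 name no gene. Library totals ran from 9653374 to 20157081 counts, and intervals and floors cover counting error only. Where a group had 0 counts, a fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% exact binomial interval. Levels are CPM, counts relative to library totals scaled by TMM factors. Coordinates are of GRCh38, from the RefSeq table.

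The symbols are listed in the order of a spreadsheet sort, and the uHL-60 columns fit a plain character sort, which puts 1343 symbols at another position. Exon bases shared with another gene on the same strand exceed 10% for 1599 symbols, and 380 have no annotation, with overlap between these sets. All of them were set aside, leaving 20357 symbols kept for comparisons with uHL-60. Counts of called genes there are given over all symbols as deposited, with the kept symbols beside them. Named genes and gene lists of dHL-60 against uHL-60, untreated or in their responses, come from the kept symbols. List medians within uHL-60 used all symbols as deposited, for members and random lists alike. Comparisons within dHL-60 used all symbols. This handling was chosen after the data were seen.

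Differences were tested with edgeR 4.0.16 (quasi-likelihood F test, two-sided, R 4.3.3) on the deposited counts, with TMM scaling, low counts removed by filterByExpr, and Benjamini-Hochberg adjustment at an adjusted p under 0.05, and every adjusted p of a gene comes from this test unless another tool is named. Comparisons within dHL-60 were contrasts of group means over its 12 libraries, which share 1 estimate of the spread. Untreated dHL-60 and uHL-60 were compared over 6 libraries with time as an additive term. There the cell state cannot be told apart from any culture or library batch shared by all uHL-60 libraries. Differences between the responses at 24 and 4 h (24 h minus 4 h), and between those of dHL-60 and uHL-60 (dHL-60 minus uHL-60, over 16 libraries), were tested as interactions. In the latter each lone uHL-60 library was assumed to vary like dHL-60 replicates. For uHL-60 with LTA against its control no test was made within a time. A test over both times, with time as an additive term over 4 libraries, was added after the data were seen. Log2 ratios of scaled counts with a prior count of 2 are given for genes of at least 5 CPM, for the genes always reported at any level, and for genes under 5 CPM that the naming rule took and that differ by 2-fold beyond their exact binomial interval.

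The 24 gene lists covered NF-κB feedback, cytokines, chemokines, interferon-stimulated genes, Toll-like receptor signalling, the inflammasome, immediate early genes, mature neutrophil genes, promyelocyte genes, the NADPH oxidase, the cell cycle, apoptosis, glycolysis and hypoxia, the unfolded protein and amino acid response, cholesterol, metallothionein and antioxidant genes, ribosome biogenesis, reference genes, and markers of macrophages, of eosinophils and basophils, of lymphocytes and of red cells and platelets. The remaining lists, mitochondrial transcripts and replication-dependent histones, had 0 members here and gave no test. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 between genes. Beside it ran camera with an estimated correlation and the directional test fry. Adjustment was over all lists and comparisons, or over the kept-symbol comparisons with uHL-60 alone. The 155 list calls with the preset correlation mix both, and none held with the estimated one. In each of the 155 the median, the mean and the test had the same sign. Members were also adjusted over the list alone, as given in parentheses. In uHL-60 the median of list members with at least 1 CPM was placed among 10000 random lists matched on expression.

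The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for each comparison, the 10 largest changes in each direction among called genes with a mean of at least 1 log2 CPM and no overlap between the libraries of the groups (a condition left out for differences of responses), passing over clone-based names. It added up to 4 members of each list by smallest adjusted p, and, where under 5 genes passed in a direction, the 5 with the smallest p as values only. TLR2, TLR1, TLR6, CD14, MYD88, ITGAM and MPO are always reported. Some genes that the rule took are not reported here. From this the text takes the first 5 in each direction (3 for dose and response differences) and the first called member of each list that passed (of 7 lists, passed or not, for dose and response differences). These numbers, and the naming in uHL-60 of NUDT4P2, FAM72D and SMN2, of the genes called over both times and of genes under 5 CPM, were set after values were seen. For uHL-60 the text gives the genes named in it for dHL-60 with 1 µg/ml LTA at the same time that have at least 5 CPM, and leaves out the 10 largest and smallest ratios that the rule also listed.

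The test was tried on simulated counts with 100 genes changed by 2-fold and 100 by 4-fold. For 1 µg/ml LTA at 4 h it recovered 71% and 98% of them over 11499 genes, with 15 false calls. For the difference between its responses at 24 and 4 h it recovered 30% and 89% over 11498 genes with 3 false calls. For untreated dHL-60 against uHL-60 it recovered 41% and 99% over 11469 genes with 10. For the 4 h response of dHL-60 against that of uHL-60 it recovered 25% and 81% over 11874 genes with 13. False calls made up 8.15%, 2.46%, 6.67% and 10.9% of the calls in these 4 simulations. The list test, simulated for 1 µg/ml LTA at 4 h, found the planted list in 20 of 20 runs with 3 false list calls. The alternatives were other scalings (DESeq2 size factors, upper quartile, library size only), no filter or a stricter filter on low counts, DESeq2 1.42.0, limma-voom, a minimum change of 2-fold, other libraries in the fit, a replicate block, other prior counts and each library left out in turn. Both treatments of the uHL-60 symbols, keeping part of them or realigning the columns, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.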

Results

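HL-60 cells grow as undifferentiated promyelocytes (uHL-60) and can be turned into neutrophil-like cells (dHL-60). Lipoteichoic acid (LTA) of Staphylococcus aureus is a cell wall glycolipid sensed through TLR2, with CD14 as a coreceptor. In all, 16 libraries were sequenced. The 12 dHL-60 libraries formed 6 groups of 2, untreated or given 1 or 10 µg/ml LTA for 4 or 24 h. The 4 uHL-60 libraries formed 4 groups of 1, untreated or given 1 µg/ml LTA for 4 or 24 h, so no value of uHL-60 with LTA has a replicate check. Libraries held 9653374 to 20157081 gene counts. The libraries of a dHL-60 pair differed by more than sampling noise in each of the 6 groups, with a chi-square per degree of freedom between 10.9 and 19.96, and all were kept as separate samples. Nothing in the labels says that the dHL-60 pairs came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Changes are given as log2 fold change ± SE, and levels as CPM, counts scaled to library size, mean ± SD of 2 libraries for dHL-60.

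The series asked how both stages answer LTA, and 7 genes were followed throughout. On GRCh38 the receptor gene TLR2 lies on chromosome 4, 153684280 to 153710637, its partners TLR1 on chromosome 4, 38787569 to 38805644 and TLR6 on chromosome 4, 38822897 to 38868390, and CD14 on chromosome 5, 140631732 to 140633701. The adaptor MYD88 lies on chromosome 3, 38138661 to 38143022, the neutrophil integrin subunit ITGAM on chromosome 16, 31259975 to 31332877, and the granule enzyme MPO on chromosome 17, 58269855 to 58280935. Counts per whole gene, over its exons, do not separate exons or untranslated regions. In untreated dHL-60 at 4 h TLR2 stood at 199 ± 7.4 CPM and CD14 at 509 ± 95.1 CPM, against 18.3 and 0.648 CPM in the uHL-60 library. For every called gene named in a comparison of 2 dHL-60 groups, and in dHL-60 against uHL-60, all libraries of 1 group lay on the same side of all libraries of the other.

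After 4 h with 1 µg/ml LTA, dHL-60 cells raised genes of NF-κB feedback, cytokines and chemokines, while the stem cell factor receptor KIT and the growth regulator MYC fell. Of NF-κB subunits, inhibitors and early targets 24 of 24 members rose and 0 fell (24 and 0 over the list alone). Of cytokines 18 of 23 members rose and 0 fell (19 and 0 over the list alone), and of chemokines 18 of 18 members rose and 0 fell (18 and 0 over the list alone). Set tests gave adjusted p = 1.2e-15 to 8.68e-12 for these 3 lists, and 0.188 to 0.229 with an estimated correlation. CSF3, the granulocyte growth factor, was 399-fold (95% counting interval 110.1 to 3300.1) higher and the cytokine IL36G 216-fold (95% counting interval 73.6 to 1051) higher, on 2 and 3 control counts. SERPINB9, an inhibitor of granzyme B, rose by 7.39 ± 0.49, the chemokine CCL20 by 6.57 ± 0.32 and the interleukin-12 subunit IL12B by 6.35 ± 0.23. CCL5 went from 35 ± 0.286 to 455 ± 47.7 CPM, a rise of 3.70 ± 0.16, and the costimulatory receptor CD40 rose by 3.44 ± 0.19. For these 7 genes the adjusted p was at most 3.09e-07. The globin gene HBB fell by 6.80 ± 0.35. CD1D, which presents lipid antigens, fell by 4.68 ± 0.24 and the lectin SIGLEC15 fell by 4.56 ± 0.37. YPEL4 fell by 4.19 ± 0.50 and the collagen gene COL9A3 fell by 3.83 ± 0.37, and the adjusted p of these 5 was at most 2.01e-05.

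Stress and metabolic genes changed as well at 4 h with 1 µg/ml. Members higher and lower, with those over the list alone in parentheses, numbered 21 and 0 of 28 (22 and 0) in immediate early genes, 18 and 3 of 30 (18 and 3) in apoptosis and 13 and 1 of 22 (13 and 1) in the unfolded protein and amino acid response. They numbered 13 and 0 of 21 (15 and 0) in cholesterol genes, 10 and 3 of 22 (10 and 3) in Toll-like receptor signalling and 5 and 0 of 8 (5 and 1) in the NADPH oxidase. Cell cycle genes had 7 and 0 of 33 (6 and 0), and metallothionein and antioxidant genes 7 and 2 of 17 (7 and 2). Lower as lists were promyelocyte genes with 1 and 6 of 23 (1 and 6), ribosome biogenesis genes with 0 and 9 of 24 (0 and 9) and markers of red cells and platelets with 1 and 4 of 7 (1 and 4). These 11 passed with adjusted p = 2.35e-08 to 0.0423, and gave adjusted p = 0.188 to 0.522 with an estimated correlation. DUSP5, a phosphatase of MAP kinases, rose by 3.55 ± 0.19, the survival factor MCL1 by 1.66 ± 0.13, and DDIT4, which restrains mTORC1, by 2.35 ± 0.24. The sterol carrier STARD4 rose by 3.03 ± 0.28, the kinase IRAK2, which acts below MYD88, by 4.03 ± 0.25, and cyclin D1 (CCND1) by 2.87 ± 0.15. The zinc importer SLC39A8 rose by 2.09 ± 0.17 and the oxidase subunit NCF1, uncertain because of near-identical copies, by 2.07 ± 0.31. KIT fell by 2.67 ± 0.20 and MYC fell by 1.65 ± 0.17, and the adjusted p of these 10 was at most 0.00014. The 8 other lists did not pass (adjusted p = 0.143 to 0.918). They had 4 and 7 of 25 (4 and 7) in interferon-stimulated genes, 5 and 3 of 11 (5 and 4) in the inflammasome, 6 and 6 of 26 (6 and 8) in mature neutrophil genes and 8 and 4 of 26 (8 and 4) in glycolysis and hypoxia. Macrophage markers had 4 and 4 of 13 (4 and 4), eosinophil and basophil markers 0 and 1 of 6 (0 and 1), lymphocyte markers 2 and 1 of 6 (2 and 1) and reference genes 3 and 2 of 23 (3 and 2).

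Among the genes followed throughout, at 4 h with 1 µg/ml TLR2 rose by 2.61 ± 0.16 (adjusted p = 9.13e-08), MYD88 by 1.32 ± 0.15 (1.09e-05) and CD14 by 0.55 ± 0.15 (0.0114). TLR6 fell by 0.76 ± 0.20 (adjusted p = 0.00762) and ITGAM fell by 0.34 ± 0.12 (0.0436). TLR1 at 0.049 ± 0.20 and MPO at -0.19 ± 0.22 were not called (adjusted p = 0.864 and 0.509). In all, 4594 of 11866 genes were called, 2214 higher and 2380 lower. Upper-quartile scaling, which moved the median of all genes by -0.12, gave 1805 higher and 3077 lower. ITGAM lost its call without any single control or treated library (replicates 1 and 2 of each, -0.30 to -0.37, adjusted p = 0.0734 to 0.165), and without control replicate 1 the fitted value of IL36G went from 7.65 to 11.58. Without control replicate 2 or treated replicate 1, TLR6 (-0.52, adjusted p = 0.0856, and -0.57, adjusted p = 0.0755) and CD14 (0.36, adjusted p = 0.0941, and 0.52, adjusted p = 0.0504) lost theirs.

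**Figure D1:**
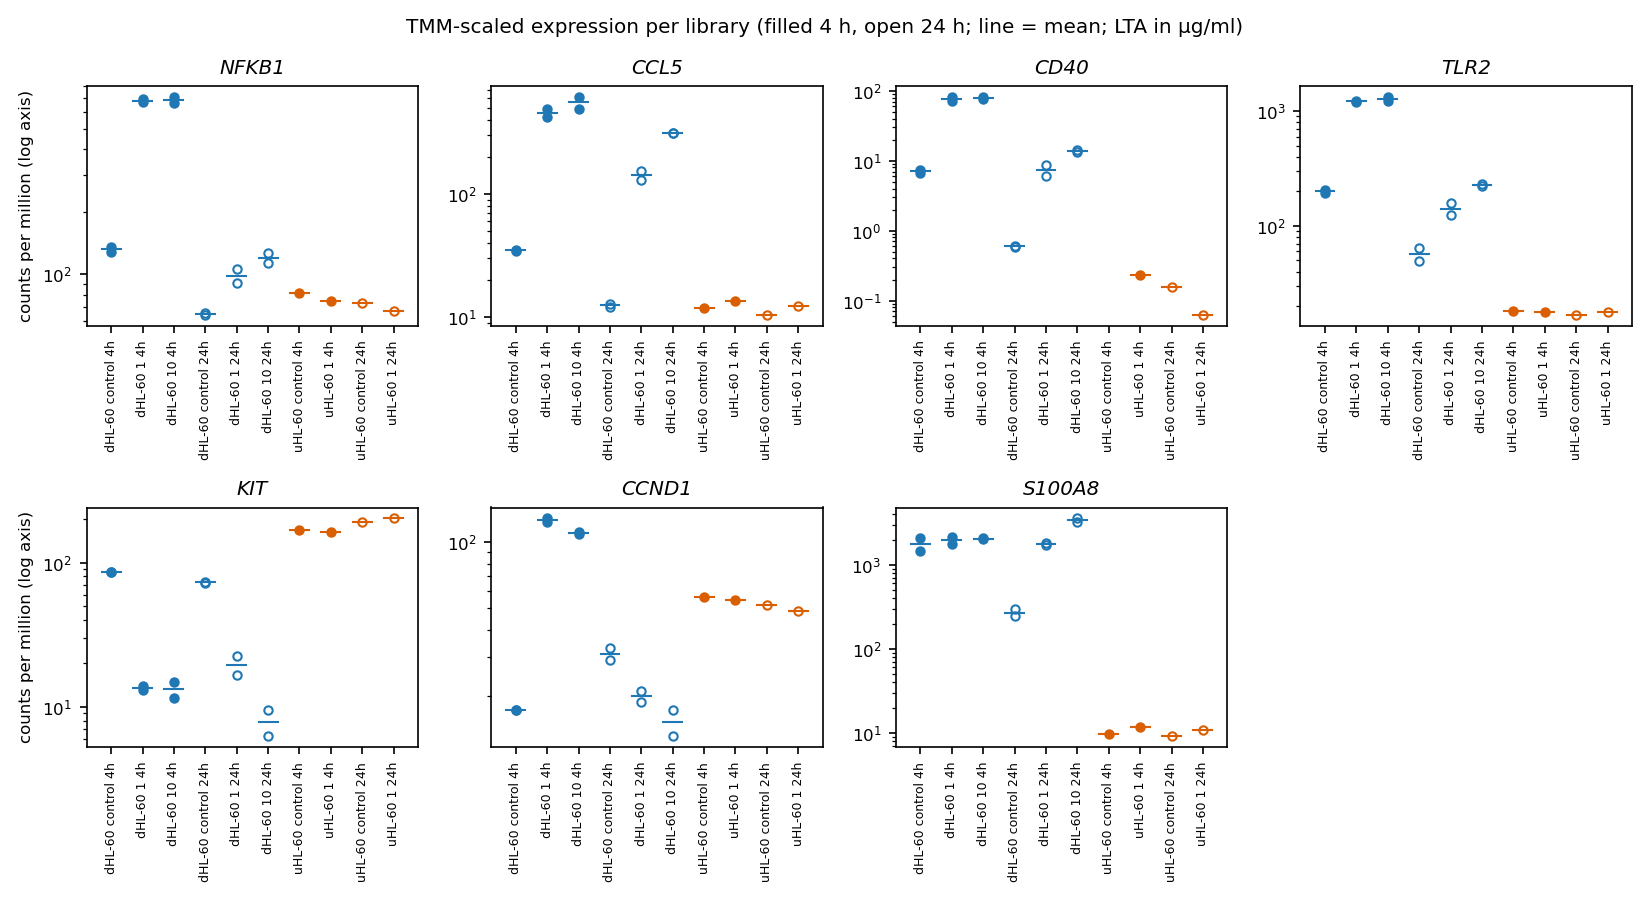
CPM of 7 genes on a log axis in each library, by group along the horizontal axis (control or LTA in µg/ml). Points at 4 h are filled and at 24 h open, and lines are group means. The uHL-60 control at 4 h, with 0 counts of CD40, is not drawn for that gene. TLR2 stood at 1216 ± 6.71 CPM in dHL-60 after 4 h with 1 µg/ml LTA and at 17.9 CPM in the uHL-60 library with LTA.

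With 10 µg/ml LTA for 4 h, NF-κB, cytokine, chemokine and cholesterol genes were higher in dHL-60, and KIT and MYC lower. In the NF-κB list 24 of 24 members rose and 0 fell (24 and 0 over the list alone). Among cytokines 19 of 23 members rose and 0 fell (19 and 0 over the list alone), among chemokines 18 of 18 members rose and 0 fell (18 and 0 over the list alone) and among cholesterol genes 16 of 21 members rose and 0 fell (16 and 0 over the list alone). The 4 set tests gave adjusted p = 2.06e-15 to 1.53e-06, and 0.188 to 0.301 with an estimated correlation. CSF3 was 533-fold (95% counting interval 147 to 4407) higher, IL36G 297-fold (95% counting interval 101 to 1444) higher and the activin subunit INHBA 148-fold (95% counting interval 50.3 to 720.2) higher, on 2, 3 and 3 control counts. SERPINB9 rose by 7.73 ± 0.49, CCL20 by 6.88 ± 0.32, IL12B by 6.60 ± 0.23 and CCL5 by 4.01 ± 0.16, to 558 ± 85.6 CPM. The receptor adaptor TRAF1 rose by 3.84 ± 0.20 and STARD4 by 3.56 ± 0.29, and the adjusted p of these 9 was at most 6.32e-07. COL9A3 fell by 4.62 ± 0.41, CD1D fell by 4.59 ± 0.24, the anion exchanger SLC4A3 fell by 4.33 ± 0.51, YPEL4 fell by 4.06 ± 0.48 and SIGLEC15 fell by 3.66 ± 0.33 (adjusted p of at most 1.96e-05).

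Other lists passed at 4 h with 10 µg/ml, with members higher and lower (over the list alone) as follows. There were 19 and 0 of 28 (21 and 0) in immediate early genes, 17 and 3 of 30 (17 and 3) in apoptosis, 12 and 1 of 22 (15 and 1) in the unfolded protein response and 9 and 2 of 17 (9 and 2) in antioxidant genes. The NADPH oxidase had 4 and 0 of 8 (4 and 0), cell cycle genes 8 and 0 of 33 (5 and 0), promyelocyte genes 0 and 8 of 23 (0 and 8) and ribosome biogenesis genes 0 and 8 of 24 (0 and 8). Set tests of these 8 gave adjusted p = 1.04e-07 to 0.0303, and 0.188 to 0.495 with an estimated correlation. DUSP5 rose by 3.83 ± 0.19, MCL1 by 1.78 ± 0.13, DDIT4 by 2.65 ± 0.24, SLC39A8 by 2.32 ± 0.18 and CCND1 by 2.69 ± 0.15. KIT fell by 2.70 ± 0.20 and MYC fell by 1.77 ± 0.17, and the adjusted p of these 7 was at most 3.22e-06. TLR2 rose by 2.69 ± 0.17, MYD88 by 1.27 ± 0.15 and CD14 by 0.44 ± 0.15, and TLR6 fell by 1.18 ± 0.20 (adjusted p = 6.44e-08, 1.46e-05, 0.0309 and 0.000405). TLR1 at -0.094 ± 0.20, ITGAM at -0.30 ± 0.12 and MPO at -0.30 ± 0.22 were not called (adjusted p = 0.731, 0.0682 and 0.285). The test called 4903 genes, 2379 higher and 2524 lower, against 1868 and 3263 with upper-quartile scaling, which moved the median of all genes by -0.13. Without treated replicate 1 it called 1645 and 1536, and without control replicate 2 INHBA went from 7.13 to 11.03. CD14 lost its call without control replicate 2 (0.25, adjusted p = 0.224) or treated replicate 2 (0.34, adjusted p = 0.187), and stood at 0.67 without control replicate 1.

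At 24 h, 1 µg/ml LTA left dHL-60 with higher chemokine, NF-κB, mature neutrophil and macrophage genes and with lower promyelocyte genes. Among chemokines 15 of 18 members rose and 0 fell (15 and 0 over the list alone), and in the NF-κB list 19 of 24 members rose and 0 fell (20 and 0 over the list alone). Among mature neutrophil genes 15 of 26 members rose and 2 fell (15 and 2 over the list alone), among macrophage markers 8 of 13 members rose and 1 fell (8 and 1 over the list alone) and among promyelocyte genes 1 of 23 members rose and 16 fell (1 and 16 over the list alone). For these 5 lists adjusted p = 8.83e-12 to 0.000369, and 0.188 to 0.232 with an estimated correlation. The tyrosine kinase JAK3 rose by 6.78 ± 0.31, the receptor SLAMF8 by 6.26 ± 0.57 and the carboxylesterase CES1 by 5.70 ± 0.32. The sulfotransferase CHST2 rose by 5.30 ± 0.51 and the protease ADAMDEC1 by 5.17 ± 0.38. CCL5 rose by 3.52 ± 0.16, from 12.5 ± 0.506 to 142 ± 17 CPM, and CD40 by 3.62 ± 0.27. C5AR1, the receptor of complement fragment C5a, rose by 2.92 ± 0.18, and the adjusted p of these 8 was at most 8.48e-06. NOG, an antagonist of bone morphogenetic proteins, fell by 3.42 ± 0.39, PLD4 fell by 3.40 ± 0.32 and the adhesion protein SDK2 fell by 2.75 ± 0.32. The mucin MUC19 fell by 2.52 ± 0.33, and the granule proteases PRTN3 and CTSG stood at -2.34 ± 0.38 and -1.79 ± 0.17 (adjusted p of at most 0.000602 for these 6).

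A further 14 lists passed at 24 h with 1 µg/ml, with adjusted p = 2.7e-09 to 0.0298, and 0.188 to 0.434 with an estimated correlation. Members higher and lower, with those over the list alone in parentheses, numbered 18 and 0 of 26 (21 and 0) in glycolysis, 18 and 2 of 33 (22 and 2) in the cell cycle, 10 and 0 of 25 (10 and 0) in interferon genes and 6 and 0 of 23 (10 and 0) in cytokines. Toll-like receptor signalling had 8 and 0 of 22 (13 and 1), the inflammasome 6 and 1 of 11 (7 and 1), immediate early genes 11 and 0 of 28 (13 and 0), the NADPH oxidase 4 and 0 of 8 (4 and 0) and apoptosis 9 and 3 of 30 (9 and 3). Cholesterol genes had 6 and 0 of 21 (10 and 0), antioxidant genes 6 and 0 of 17 (7 and 0), ribosome biogenesis 0 and 5 of 24 (0 and 8), lymphocyte markers 2 and 0 of 6 (3 and 0) and markers of red cells and platelets 3 and 0 of 7 (3 and 0). EBI3, an interleukin-27 subunit, rose by 4.49 ± 0.29, PARP9 by 1.60 ± 0.17, caspase-1 (CASP1) by 1.64 ± 0.15 and the phosphatase DUSP4 by 1.66 ± 0.15. The cell cycle factor FOXM1 rose by 0.95 ± 0.12, the TNF receptor TNFRSF1B by 1.55 ± 0.14, the glucose transporter SLC2A3 by 2.49 ± 0.17 and the sterol regulator SREBF1 by 0.82 ± 0.15. The granule protein NKG7 rose by 3.75 ± 0.20 and ferritin heavy chain FTH1, uncertain because of processed copies, by 3.29 ± 0.24. MYC fell by 0.81 ± 0.17, and the adjusted p of these 11 was at most 0.00369. HBB was at least 12.6-fold higher (adjusted p = 0.000139), at 1.18 ± 0.207 CPM against 0 control counts and a floor of 3 counts over the group. TLR2 rose by 1.32 ± 0.16, TLR1 by 1.57 ± 0.20, TLR6 by 1.27 ± 0.20, CD14 by 2.07 ± 0.16, MYD88 by 0.91 ± 0.15 and ITGAM by 1.61 ± 0.12. MPO fell by 1.21 ± 0.22, with an adjusted p of at most 0.00149 for these 7. The test called 2513 genes, 1651 higher and 862 lower, against 1441 and 1179 with upper-quartile scaling. It called 917 and 222 without treated replicate 1, where MYC lost its call (-0.68, adjusted p = 0.0646), 1293 and 465 without treated replicate 2, and 1026 and 425, and 1108 and 485, without control replicates 1 and 2.

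With 10 µg/ml LTA for 24 h, cholesterol and chemokine genes rose in dHL-60 and ribosome biogenesis genes fell. Among cholesterol genes 21 of 21 members rose and 0 fell (21 and 0 over the list alone), and among chemokines 17 of 18 members rose and 0 fell (17 and 0 over the list alone). In the NF-κB list 23 of 24 members rose and 0 fell (23 and 0 over the list alone), among interferon genes 19 of 25 members rose and 0 fell (20 and 0 over the list alone) and in ribosome biogenesis 0 of 24 members rose and 21 fell (0 and 22 over the list alone). The 5 lists had adjusted p = 5.04e-12 to 1.41e-06, and 0.188 to 0.246 with an estimated correlation. MVD, an enzyme of sterol synthesis, rose by 2.33 ± 0.17, SLAMF8 by 7.30 ± 0.56, JAK3 by 7.17 ± 0.31, the chemokine CCL7 by 7.17 ± 0.35 and CES1 by 6.85 ± 0.32. The interleukin-7 receptor IL7R was 314-fold (95% counting interval 86.5 to 2599) higher, on 2 control counts. CCL5 rose by 4.68 ± 0.17 to 315 ± 1.4 CPM, CD40 by 4.52 ± 0.26 and the interferon regulator IRF7 by 2.17 ± 0.18, and the adjusted p of these 9 was at most 8.43e-07. SDK2 fell by 3.94 ± 0.36, PRTN3 fell by 3.25 ± 0.39 and KIT fell by 3.17 ± 0.21. The mTOR inhibitor DEPTOR stood at -3.15 ± 0.32, the flippase ATP8A1 at -2.79 ± 0.39 and MYC at -1.41 ± 0.17, all lower (adjusted p of at most 7.39e-05 for these 6).

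At 24 h with 10 µg/ml, 14 more lists passed, with adjusted p = 3.18e-08 to 0.0435, and 0.188 to 0.262 with an estimated correlation. Members higher and lower, with those over the list alone in parentheses, numbered 17 and 0 of 26 (18 and 0) in mature neutrophil genes, 9 and 2 of 13 (10 and 2) in macrophage markers, 2 and 16 of 23 (2 and 16) in promyelocyte genes and 16 and 1 of 23 (18 and 1) in cytokines. Toll-like receptor signalling had 12 and 1 of 22 (12 and 1), the inflammasome 7 and 1 of 11 (7 and 1), immediate early genes 22 and 0 of 28 (22 and 0), the NADPH oxidase 7 and 0 of 8 (7 and 0) and the cell cycle 18 and 1 of 33 (19 and 2). Apoptosis had 16 and 3 of 30 (16 and 3), glycolysis 22 and 0 of 26 (22 and 0), antioxidant genes 10 and 1 of 17 (10 and 2), lymphocyte markers 2 and 1 of 6 (2 and 1) and markers of red cells and platelets 5 and 0 of 7 (5 and 0). C5AR1 rose by 3.92 ± 0.18, EBI3 by 6.32 ± 0.29, CASP1 by 2.22 ± 0.15 and DUSP4 by 2.09 ± 0.15. Thymidine kinase TK1 rose by 1.66 ± 0.16, TNFRSF1B by 2.47 ± 0.14, SLC2A3 by 2.69 ± 0.17, NKG7 by 4.68 ± 0.21 and FTH1, with its processed copies, by 4.83 ± 0.26. The platelet receptor GP1BA was 40.1-fold (95% counting interval 10.7 to 338) higher, on 2 control counts, and the adjusted p of these 10 was at most 1.81e-05. TLR2 rose by 2.02 ± 0.16, TLR1 by 1.42 ± 0.20, TLR6 by 1.15 ± 0.20, CD14 by 3.21 ± 0.16, MYD88 by 1.29 ± 0.15 and ITGAM by 1.91 ± 0.13. MPO fell by 1.75 ± 0.22, with an adjusted p of at most 0.00047 for these 7. The test called 5056 genes, 2797 higher and 2259 lower, against 2484 and 2694 with upper-quartile scaling. Without control replicate 1 it called 2058 and 1470 and the fitted value of GP1BA went from 5.16 to 7.95.

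**Figure D2:**
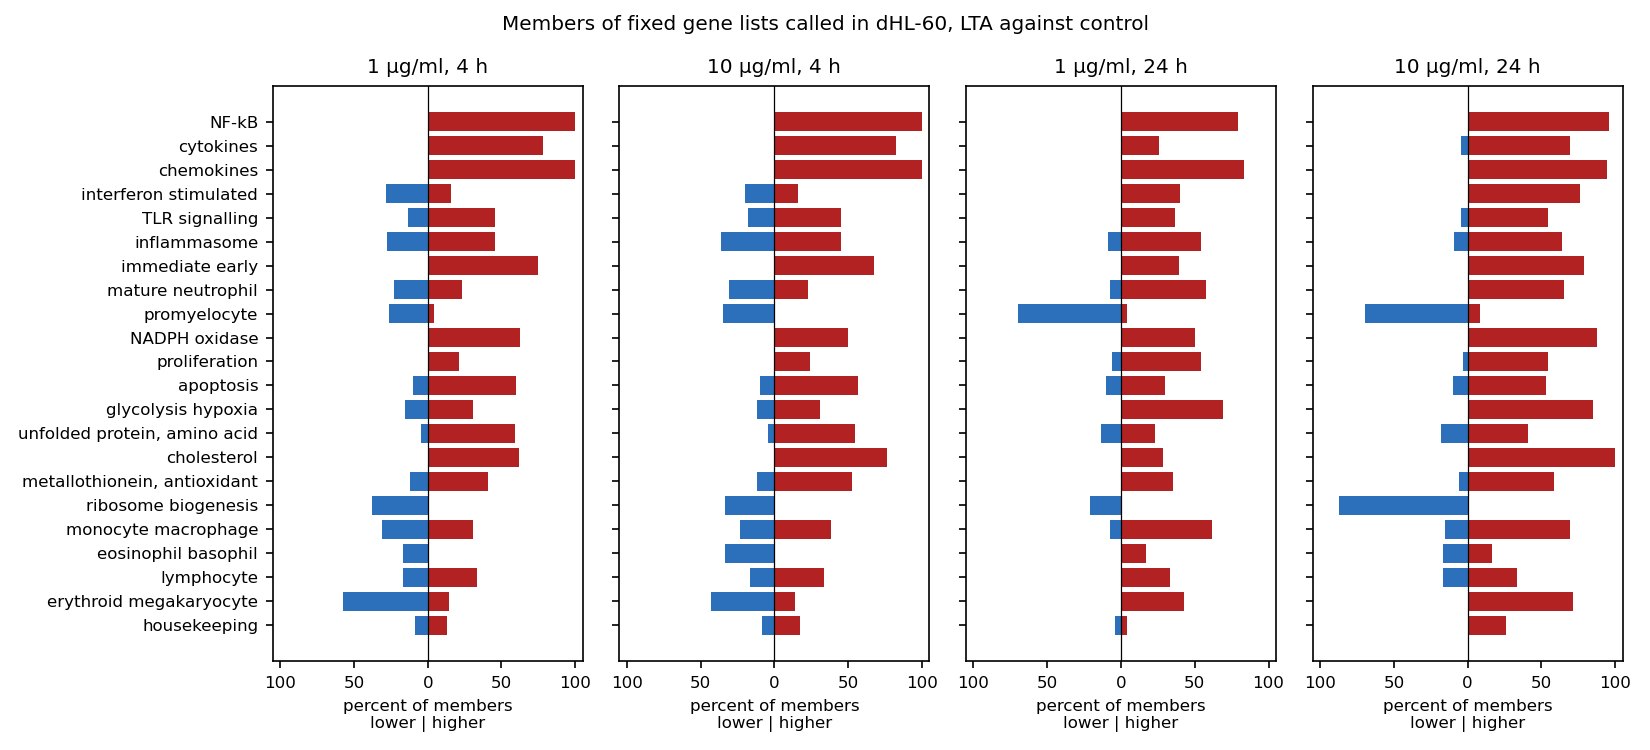
Percent of the tested members of each gene list called higher (bars to the right of 0) and lower (bars to the left) in the 4 comparisons of dHL-60 with LTA against control, 1 panel per dose and time. At 4 h the bars of NF-κB genes, 24 of 24, and chemokines, 18 of 18, reach the full width at both doses. Those of cholesterol genes, 21 of 21, do at 24 h with 10 µg/ml.

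**Figure D3:**
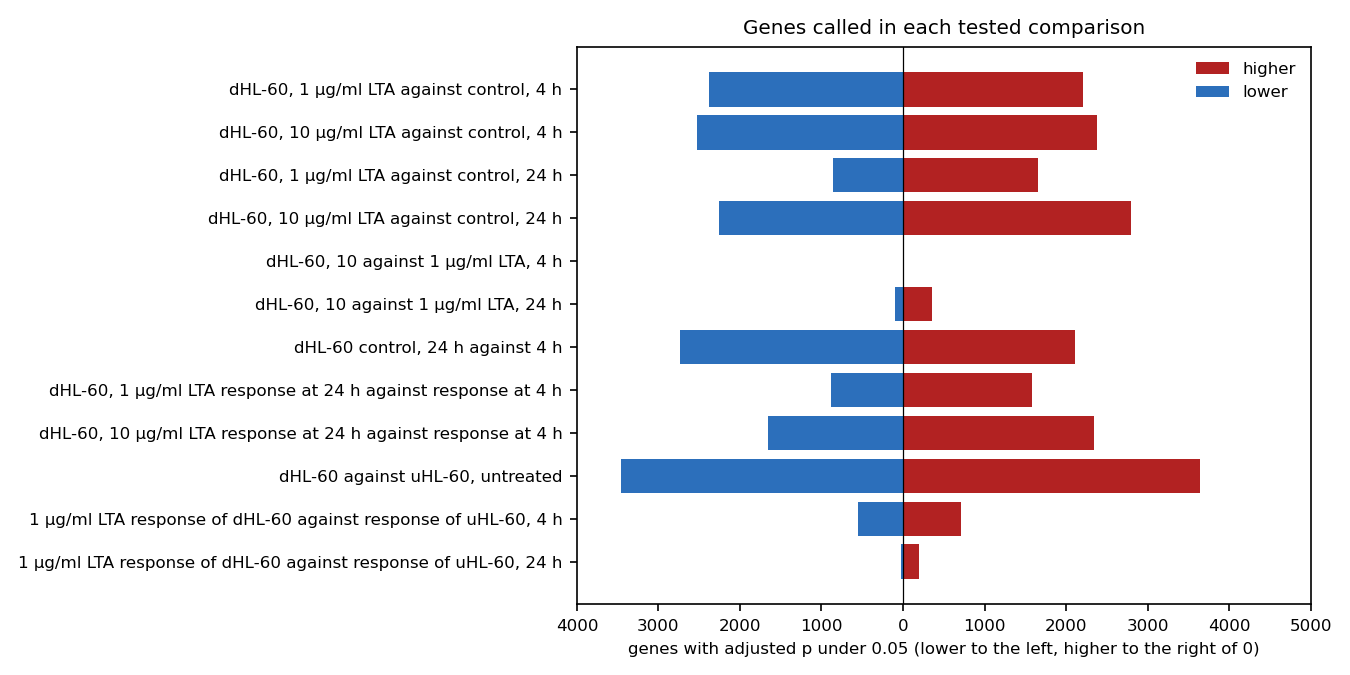
Genes called higher (right of 0) and lower (left) at an adjusted p under 0.05 in the 12 tested comparisons, over all symbols. Totals run from 1 gene for 10 against 1 µg/ml LTA at 4 h to 7102 (6142 over the kept symbols) for dHL-60 against uHL-60.

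Between the 2 doses 1 gene passed at 4 h, the globin gene HBB, 6.22 ± 0.35 higher at 10 µg/ml (adjusted p = 3.85e-06), with 22 ± 1.84 against 0.324 ± 0.235 CPM, while untreated cells held 33.5 ± 2.14 CPM. edgeR gave 216 genes at an unadjusted p under 0.05, DESeq2 called 2 genes and limma-voom 1. The genes with the smallest p above were EIF3CL, uncertain because of a near-identical copy, at 2.35 ± 0.36 (adjusted p = 0.0846), the sterol enzymes IDI1 at 0.78 ± 0.21 and FDPS at 0.50 ± 0.14, and haem oxygenase HMOX1 at 0.98 ± 0.28. Those below were GET4 at -0.97 ± 0.21, the oxygen sensor EGLN1 at -1.16 ± 0.27, IER5L at -0.93 ± 0.23, TPGS1 at -0.84 ± 0.22 and C8orf82 at -0.80 ± 0.23, with adjusted p = 1 for all these but EIF3CL. Cholesterol genes had 0 higher and 0 lower of 21 (3 and 0 over the list alone) and passed as a list with adjusted p = 9.01e-11, and 0.232 with an estimated correlation. Chemokines at 0 higher and 0 lower of 18 (0 and 0 over the list alone), cytokines at 0 higher and 0 lower of 23 (0 and 0 over the list alone) and markers of red cells, with HBB among them, at 1 higher and 0 lower of 7 (2 and 0 over the list alone) passed too. These 3 gave adjusted p = 7.36e-06 to 0.0232, and 0.188 to 0.393 with an estimated correlation. TLR2 at 0.084 ± 0.15, TLR1 at -0.14 ± 0.20, TLR6 at -0.41 ± 0.21, CD14 at -0.10 ± 0.15, MYD88 at -0.059 ± 0.14, ITGAM at 0.040 ± 0.12 and MPO at -0.11 ± 0.22 were not called (adjusted p = 1). Without replicate 2 of 10 µg/ml the test called 2 genes.

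At 24 h the higher dose gave higher levels of chemokine, NF-κB and cholesterol genes. Among chemokines 12 of 18 were higher and 0 lower (15 and 0 over the list alone), in the NF-κB list 11 of 24 were higher and 0 lower (22 and 0 over the list alone) and among cholesterol genes 9 of 21 were higher and 0 lower (19 and 0 over the list alone). Their set tests gave adjusted p = 5.04e-12 to 1.02e-11, and 0.188 to 0.232 with an estimated correlation. Another 12 lists passed, with members higher and lower (over the list alone) numbering 7 and 0 of 23 (13 and 1) in cytokines, 4 and 0 of 25 (8 and 0) in interferon genes, 3 and 1 of 11 (4 and 1) in the inflammasome and 4 and 0 of 28 (12 and 0) in immediate early genes. There were 7 and 0 of 26 (11 and 0) in mature neutrophil genes, 5 and 0 of 13 (5 and 0) in macrophage markers, 3 and 0 of 8 (4 and 0) in the NADPH oxidase and 3 and 0 of 30 (4 and 0) in apoptosis. There were 1 and 0 of 26 (3 and 0) in glycolysis, 2 and 0 of 22 (7 and 0) in the unfolded protein response, 3 and 0 of 17 (7 and 1) in antioxidant genes and 0 and 4 of 24 (0 and 10) in ribosome biogenesis. These 12 gave adjusted p = 3.92e-08 to 0.0355, and 0.188 to 0.266 with an estimated correlation. Promyelocyte genes had 0 and 1 of 23 (1 and 3) and did not pass (adjusted p = 0.138). CCL20 was higher by 3.39 ± 0.47 at 10 µg/ml, the adhesion receptor ADGRG3 by 2.80 ± 0.30, CCL1 by 2.61 ± 0.43, CCL7 by 2.38 ± 0.21 and the NF-κB target IER3 by 2.11 ± 0.28. EBI3 was higher by 1.83 ± 0.22, FDPS by 1.40 ± 0.14, C5AR1 by 1.00 ± 0.16 and the interferon regulator IRF1 by 0.79 ± 0.17. The sterol exporter ABCA1 was lower at -2.17 ± 0.33, the coagulation factor gene F13A1 at -1.84 ± 0.44, DEPTOR at -1.40 ± 0.35 and KIT at -1.28 ± 0.21, and the adjusted p of these 13 was at most 0.0417. CD14 was higher by 1.14 ± 0.15 and TLR2 by 0.70 ± 0.16 (adjusted p = 0.00147 and 0.0277). TLR1 at -0.15 ± 0.19, TLR6 at -0.12 ± 0.19, MYD88 at 0.38 ± 0.14, ITGAM at 0.29 ± 0.12 and MPO at -0.54 ± 0.22 were not called (adjusted p = 0.148 to 0.74). The test called 453 genes, 359 higher and 94 lower, against 771 and 583 with no filter, 553 and 200 with DESeq2 and 533 and 172 with only the 6 libraries of the time point. It called 45 and 4 without 1 µg/ml replicate 2, 170 and 21 without 1 µg/ml replicate 1, 71 and 2 without 10 µg/ml replicate 1 and 390 and 272 without 10 µg/ml replicate 2. Without 1 µg/ml replicate 2, calls ended for CCL20 (2.99), CCL1 (2.23), F13A1 (-0.97), DEPTOR (-1.01), IRF1 (0.91), C5AR1 (0.82) and TLR2 (0.52). Without 10 µg/ml replicate 1 they ended for CCL1 (1.96), F13A1 (-1.42), DEPTOR (-1.24), IRF1 (0.71), C5AR1 (0.77), KIT (-1.04) and TLR2 (0.70). DEPTOR (-1.63) and TLR2 (0.67) also lost theirs without 10 µg/ml replicate 2, and IRF1 (0.68) without 1 µg/ml replicate 1.

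The calls of both doses overlapped at each time. At 4 h, 2044 genes were higher and 2089 lower at both doses and 0 went opposite ways, against 444 and 506 for independent lists of these sizes. At 24 h, 1562 were higher and 795 lower at both doses and 0 opposite, against 389 and 164. In 30 simulations of unchanged groups against the same controls the overlap averaged 0.0333 genes at each time and was at most 1. Across genes, which are not independent replicates, the fold changes of both doses correlated at r = 0.949 at 4 h and 0.900 at 24 h, against 0.494 and 0.469 in the simulations. The covariance was 1.16 and 0.882, against 0.0449 and 0.0510 simulated. Both doses share 2 control libraries, which were not divided between them, so part of the excess may come from these. With almost no calls, the simulations cannot size that part.

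Untreated dHL-60 changed between 4 and 24 h: chemokine, NF-κB and mature neutrophil genes were lower at 24 h and ribosome biogenesis genes higher. Among chemokines 0 of 18 were higher and 14 lower (0 and 14 over the list alone) at 24 h, and in the NF-κB list 0 of 24 were higher and 21 lower (0 and 21 over the list alone). Among mature neutrophil genes 0 of 26 were higher and 22 lower (1 and 23 over the list alone), and in ribosome biogenesis 20 of 24 were higher and 0 lower (21 and 0 over the list alone). These lists had adjusted p = 9.01e-11 to 6.66e-08, and 0.188 to 0.233 with an estimated correlation. HBB was at least 358-fold lower at 24 h, with 0 counts there and a floor of 3 counts over the group. OLR1, a receptor of oxidised LDL, was 952-fold (95% counting interval 170.2 to 37642) lower on 1 count at 24 h. C15orf48 fell by 6.50 ± 0.30, the kinesin KIFC3 fell by 6.17 ± 0.48 and the chemokine CCL4, uncertain because of near-identical copies, fell by 5.98 ± 0.49. CXCL16 fell by 3.72 ± 0.21, TRAF1 fell by 3.30 ± 0.21 and C5AR1 fell by 2.62 ± 0.18, and the adjusted p of these 8 was at most 1.62e-06. PRG2, eosinophil major basic protein, rose by 3.94 ± 0.44, the surrogate light chain gene IGLL1 by 3.358 ± 0.38 and the mitochondrial peptidase gene IMMP2L by 2.95 ± 0.42. PRTN3 rose by 2.78 ± 0.38, CA8 by 2.67 ± 0.32 and the chaperone HSPD1 by 1.41 ± 0.16 (adjusted p of at most 0.000118 for these 6).

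Between the untreated times 9 further lists passed, with adjusted p = 2.52e-07 to 0.0315, and 0.192 to 0.54 with an estimated correlation. Members higher and lower at 24 h, with those over the list alone in parentheses, numbered 0 and 14 of 23 (0 and 15) in cytokines, 0 and 14 of 25 (0 and 17) in interferon genes and 0 and 9 of 22 (0 and 11) in Toll-like receptor signalling. The inflammasome had 0 and 8 of 11 (1 and 8), immediate early genes 0 and 21 of 28 (0 and 23), promyelocyte genes 7 and 1 of 23 (7 and 1), the NADPH oxidase 0 and 7 of 8 (0 and 7), apoptosis 2 and 13 of 30 (2 and 15) and markers of red cells and platelets 0 and 4 of 7 (0 and 4). IL1A fell by 5.14 ± 0.35, IRF1 fell by 1.62 ± 0.17, and NINJ1, a mediator of membrane rupture, fell by 2.44 ± 0.21. PPP1R15A fell by 2.30 ± 0.23 and the survival gene BCL2A1 fell by 3.09 ± 0.24, while calreticulin (CALR) rose by 1.78 ± 0.18 (adjusted p of at most 9.2e-06 for these 6). TLR2 fell by 1.81 ± 0.16, TLR1 fell by 0.98 ± 0.20, TLR6 fell by 1.496 ± 0.20, CD14 fell by 1.84 ± 0.16, MYD88 fell by 0.93 ± 0.15 and ITGAM fell by 0.93 ± 0.12. MPO rose by 0.94 ± 0.22, with an adjusted p of at most 0.00398 for these 7. The test called 4853 genes, 2114 higher and 2739 lower at 24 h, but 1274 and 1864 without the 24 h replicate 1.

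The response to 1 µg/ml LTA differed between 24 and 4 h, with less response of cytokine and NF-κB genes at 24 h and more of mature neutrophil genes. Each response is measured against the control of its own time, and mature neutrophil genes were lower in untreated cells at 24 h. A larger response at 24 h is therefore not in itself a higher level than at 4 h. In this difference of responses 0 of 23 were higher and 10 lower (0 and 10 over the list alone) among cytokines. In the NF-κB list 0 of 24 were higher and 13 lower (0 and 13 over the list alone), and among mature neutrophil genes 14 of 26 were higher and 0 lower (14 and 1 over the list alone). The 3 lists passed with adjusted p = 5.35e-09 to 2.81e-05, and 0.188 to 0.307 with an estimated correlation. Another 8 lists passed, with members higher and lower (over the list alone) numbering 1 and 4 of 18 (1 and 4) in chemokines, 8 and 1 of 25 (11 and 1) in interferon genes, 2 and 6 of 28 (2 and 7) in immediate early genes and 2 and 10 of 30 (4 and 13) in apoptosis. There were 11 and 3 of 26 (14 and 3) in glycolysis, 1 and 8 of 22 (1 and 11) in the unfolded protein response, 6 and 2 of 13 (6 and 2) in macrophage markers and 3 and 0 of 7 (4 and 0) in markers of red cells and platelets. These 8 gave adjusted p = 0.000926 to 0.0344, and 0.188 to 0.477 with an estimated correlation. Promyelocyte genes had 1 and 6 of 23 (2 and 8) and cholesterol genes 0 and 2 of 21 (0 and 2) and did not pass (adjusted p = 0.0872 to 0.358). NFKB1 differed by -1.75 ± 0.18, IL1B by -2.41 ± 0.44, the microRNA-155 host gene MIR155HG by -7.69 ± 0.79, CCL20 by -5.04 ± 1.32 and NMNAT3 by -3.99 ± 0.36. The endocytic adaptor DAB2 differed by 5.34 ± 0.75, the inhibitory IgG receptor FCGR2B by 5.33 ± 1.12, YPEL4 by 5.32 ± 0.61, CXCL16 by 1.52 ± 0.26, PARP9 by 2.39 ± 0.25 and ITGAM by 1.95 ± 0.17. CTSG differed by -1.61 ± 0.24 and STARD4 by -2.25 ± 0.38, and the adjusted p of these 13 was at most 0.0152. TLR2 at -1.29 ± 0.22 and MPO at -1.02 ± 0.31 responded lower at 24 h, and TLR1 at 1.52 ± 0.28, TLR6 at 2.03 ± 0.28 and CD14 at 1.52 ± 0.22 higher (adjusted p of at most 0.0314). MYD88 at -0.41 ± 0.20 was not called (adjusted p = 0.178). The test called 2461 genes, 1582 higher and 879 lower at 24 h, but 1064 and 550 without the 24 h control replicate 1 and 1151 and 547 without the 24 h treated replicate 2. FCGR2B lost its call without the 4 h control replicate 2 (3.42) and stood at 9.65 without the 4 h treated replicate 2, and CCL20 lost its call without the 24 h control replicate 2 (-4.30). MPO lost its call without control replicate 2 at 4 h (-0.82) or 24 h (-0.81), treated replicate 1 or 2 at 4 h (-0.98 and -1.08) or treated replicate 1 at 24 h (-0.79).

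With 10 µg/ml LTA and the same controls, the response at 24 h exceeded that at 4 h for mature neutrophil and interferon-stimulated genes. Among mature neutrophil genes 16 of 26 were higher and 0 lower (17 and 0 over the list alone), and among interferon genes 16 of 25 were higher and 1 lower (16 and 1 over the list alone). Both passed with adjusted p = 6.66e-08 to 0.000142, and 0.188 to 0.256 with an estimated correlation. Macrophage markers had 6 higher and 2 lower of 13 (8 and 2 over the list alone), glycolysis genes 15 higher and 2 lower of 26 (15 and 2 over the list alone) and ribosome biogenesis genes 0 higher and 8 lower of 24 (0 and 9 over the list alone). These 3 gave adjusted p = 0.000647 to 0.00527, and 0.232 to 0.247 with an estimated correlation. Another 4 lists passed, with members higher and lower (over the list alone) numbering 2 and 4 of 23 (1 and 2) in cytokines, 4 and 0 of 8 (5 and 0) in the NADPH oxidase, 2 and 0 of 6 (2 and 0) in lymphocyte markers and 3 and 0 of 7 (5 and 0) in markers of red cells and platelets. These 4 gave adjusted p = 0.00106 to 0.047, and 0.192 to 0.395 with an estimated correlation. The NF-κB list had 3 and 5 of 24 (3 and 6), chemokines 5 and 0 of 18 (3 and 0), promyelocyte genes 1 and 8 of 23 (1 and 9) and cholesterol genes 8 and 2 of 21 (8 and 2) and did not pass (adjusted p = 0.0589 to 0.69). HBB differed by 6.94 ± 0.99, DAB2 by 6.78 ± 0.86, the inhibitory receptor LILRB1 by 6.41 ± 0.64, C5AR1 by 3.62 ± 0.24, CXCL16 by 2.58 ± 0.26, EBI3 by 2.55 ± 0.36 and PARP9 by 2.42 ± 0.25. MIR155HG differed by -6.64 ± 0.72, the fatty acid elongase ELOVL7 by -5.64 ± 0.83, IL12B by -4.29 ± 1.46, STARD4 by -2.12 ± 0.38, CTSG by -1.89 ± 0.24 and NFKB1 by -1.49 ± 0.18, and the adjusted p of these 13 was at most 0.0371. TLR1 differed by 1.51 ± 0.28, TLR6 by 2.32 ± 0.28, CD14 by 2.77 ± 0.22, ITGAM by 2.20 ± 0.18, TLR2 by -0.68 ± 0.22 and MPO by -1.45 ± 0.31 (adjusted p of at most 0.0316), and MYD88 at 0.026 ± 0.20 was not called (adjusted p = 0.937). The test called 4001 genes, 2339 higher and 1662 lower at 24 h, but 1597 and 1063 without the 4 h treated replicate 1 and 1661 and 1049 without the 24 h control replicate 1. The values of HBB, DAB2 and IL12B rest on groups of at most 3 counts and so on the prior count. DAB2 stood at 10.74 without the 4 h treated replicate 2. IL12B was not called without the control replicates 1 at 4 h (-4.33) or 24 h (-1.51) or the treated replicates 1 at 4 h (-4.23) or 24 h (-4.08). TLR2 was not called without those 4 libraries (-0.66, -0.46, -0.64 and -0.71) or the 24 h treated replicate 2 (-0.71).

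Averaged over 4 and 24 h, untreated dHL-60 had lower cell cycle genes than uHL-60 and higher mature neutrophil, chemokine and macrophage genes. Controls of dHL-60 changed in 4853 genes between these times, and folds per time are not given. Members higher and lower in dHL-60 (over the list alone) numbered 0 and 31 of 31 (0 and 31) in the cell cycle. They numbered 21 and 0 of 24 (21 and 0) in mature neutrophil genes, 16 and 0 of 16 (16 and 0) in chemokines. Macrophage markers had 9 and 1 of 11 (9 and 1). For these 4 lists adjusted p = 2.64e-12 to 0.00349, and 0.196 to 0.522 with an estimated correlation. The spindle checkpoint kinase BUB1B was lower at -3.01 ± 0.18, the integrin subunit ITGAX higher by 7.62 ± 0.36 and CCL2 higher by 6.94 ± 0.39. Some genes had 0 uHL-60 counts, against a floor of 3 counts over the group. AQP9, a glycerol channel, was at least 317-fold higher, the scavenger receptor COLEC12 at least 291-fold, EBI3 at least 173-fold and MIR1244-2 at least 311-fold. MTRNR2L8 was 16535-fold (95% counting interval 5658 to 80184) lower, on 3 dHL-60 counts, PKD1P1 stood at -8.45 ± 0.42, the defensin DEFA1 at -8.24 ± 0.49, PWP2 at -7.78 ± 0.32 and EIF3CL at -7.40 ± 0.48. MIR1244-2, MTRNR2L8, PKD1P1, DEFA1, PWP2 and EIF3CL have near-identical copies and are uncertain, and the adjusted p of these 12 was at most 6.95e-05.

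Between untreated dHL-60 and uHL-60, 8 further lists passed, with adjusted p = 6.82e-05 to 0.0347, and 0.419 to 0.61 with an estimated correlation. Members higher and lower in dHL-60, with those over the list alone in parentheses, numbered 16 and 0 of 22 (17 and 0) in the NF-κB list, 14 and 0 of 18 (14 and 0) in cytokines, 11 and 2 of 22 (11 and 2) in Toll-like receptor signalling and 6 and 0 of 10 (6 and 0) in the inflammasome. Immediate early genes had 21 and 0 of 27 (22 and 0), the NADPH oxidase 5 and 0 of 8 (6 and 0), cholesterol genes 1 and 9 of 20 (1 and 9) and ribosome biogenesis 0 and 13 of 20 (0 and 13). The adhesion molecule ICAM1 was higher by 6.96 ± 0.50 and JUN by 4.59 ± 0.40, and NLRP1 was 342-fold (95% counting interval 117 to 1660.0) higher on 3 uHL-60 counts. The sterol enzyme CYP51A1, uncertain because of copies, was lower at -5.58 ± 0.39 and the nucleolar methyltransferase FBL at -1.95 ± 0.25 (adjusted p of at most 0.000335 for these 5). CD14 was higher by 9.09 ± 0.37, TLR2 by 2.48 ± 0.38, TLR1 by 1.85 ± 0.33, TLR6 by 2.87 ± 0.42, MYD88 by 2.56 ± 0.29 and ITGAM by 5.72 ± 0.41. MPO was lower at -1.04 ± 0.27, with an adjusted p of at most 0.0111 for these 7. The test called 7102 of 11986 genes, 3648 higher and 3454 lower, and upper-quartile scaling moved the median of all genes by 0.12. Over the kept symbols, from which the genes and lists named here come, it called 6142 of 10779. Of these 6021 were also called over all symbols. The kept symbols still hold genes with near-identical copies, CYP51A1 among them, so calls and lists, as of cholesterol genes, may partly reflect counting. MPO lost its call without the 24 h dHL-60 replicate 1 (-1.002, adjusted p = 0.0622) or the 4 h uHL-60 library (-0.54, adjusted p = 0.158). Without that uHL-60 library TLR1 stood at 1.23 and the fitted value of AQP9 went from 11.83 to 7.87.

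In uHL-60, few genes of at least 5 CPM differed by 2-fold with 1 µg/ml LTA, in 1 library against 1 with no replicate check. At 4 h 2 of 8890 such genes differed by at least 2-fold, and at 24 h 7 of 8964. Over the kept symbols there were 1 at 4 h, NUDT4P2 at 2.27, and 2 at 24 h, FAM72D at 2.35 and SMN2 at -1.70. All have near-identical copies. Over both times, with time as an additive term and 1 residual degree of freedom, edgeR called LTA in 9 of 9971 kept genes, 5 higher and 4 lower, and in 23 of 11020 over all symbols. Of the 9, the mature neutrophil gene MMP9 rose by 2.04 ± 0.49 and JAML by 1.15 ± 0.26 (adjusted p = 0.0299 and 0.018). The spread of the log2 ratio over genes (SD) was 0.116 at 4 h and 0.187 at 24 h. CCL5 had a log2 ratio of 0.17 (-0.099 to 0.43) at 4 h and 0.23 (-0.057 to 0.52) at 24 h, with the 95% exact binomial interval for counting error in parentheses. At 4 h KIT had -0.060 (-0.13 to 0.012), CCND1 -0.052 (-0.18 to 0.074), STARD4 -0.11 (-0.37 to 0.16), MYC 0.10 (0.080 to 0.12) and SERPINB9 -0.056 (-0.40 to 0.29). MCL1 had 0.055 (-0.025 to 0.13), DDIT4 0.10 (-0.18 to 0.38), SLC39A8 0.050 (-0.033 to 0.13) and NCF1, with its copies, 0.53 (0.29 to 0.78). At 24 h CTSG had -0.12 (-0.20 to -0.053), PRTN3 -0.24 (-0.26 to -0.22), SDK2 -0.20 (-0.35 to -0.047), SREBF1 0.075 (-0.062 to 0.21) and CASP1 0.071 (-0.11 to 0.25). MYC had -0.14 (-0.17 to -0.12), TNFRSF1B -0.16 (-0.27 to -0.054), FOXM1 -0.075 (-0.18 to 0.029), SLC2A3 0.29 (-0.056 to 0.65), PARP9 0.033 (-0.24 to 0.31), NKG7 -0.30 (-0.66 to 0.053) and FTH1, with its processed copies, -0.018 (-0.13 to 0.093). TLR2 had -0.035 (-0.26 to 0.19) and 0.078 (-0.16 to 0.31), TLR1 -0.33 (-0.85 to 0.17) and -0.098 (-0.54 to 0.33), and TLR6 -0.15 (-0.80 to 0.48) and -0.15 (-0.75 to 0.42). MYD88 had 0.11 (-0.076 to 0.30) and 0.015 (-0.17 to 0.20), ITGAM 0.18 (-0.70 to 1.10) and 0.0072 (-0.69 to 0.70), and MPO -0.010 (-0.017 to -0.0043) and -0.15 (-0.16 to -0.14). CD14, with 13 control counts at 4 h and 3 LTA counts at 24 h, had 1.05 (0.19 to 2.29) and -0.75 (-3.69 to 0.92). Under 5 CPM, of 5518 genes with counts at 4 h, 89 were at least 2-fold higher and 71 lower with an interval that excluded 0, and of 5481 at 24 h, 90 and 65, with no adjustment for the number of genes. Those that the naming rule had taken for dHL-60 at the same time were CD14 and EBI3 at 4 h and HBB, IL1RN and MEFV at 24 h, all higher with LTA. EBI3 had 11 against 0 counts at 4 h, a log2 ratio of 2.43 with a lower bound of 1.53, and 0 counts in both libraries at 24 h. HBB had 27 against 2 counts, 2.89 (2.04 to 7.15), IL1RN 1.05 (0.22 to 2.19) and MEFV 1.64 (0.37 to 5.83). The NF-κB list had a median log2 ratio of -0.0618 at 4 h, at percentile 10.9 of 10000 matched random lists, and -0.0967 at 24 h, at percentile 2.48. Chemokines, with 3 members of at least 1 CPM, had 0.165 (percentile 93.5) and 0.231 (percentile 90.5), and cholesterol genes -0.132 (percentile 0, below every random list) and 0.0693 (percentile 97.6). Of 22 lists, the others outside percentiles 2.5 to 97.5 were at 4 h mature neutrophil genes at 0.0966 (percentile 99.6), promyelocyte genes at 0.024 (percentile 99.5) and ribosome biogenesis at 0.0191 (percentile 99.7). At 24 h they were the unfolded protein response at -0.0987 (percentile 0.73) and glycolysis at -0.0878 (percentile 1.23). These percentiles used all symbols as deposited, with those set aside elsewhere, and describe the libraries, not the conditions.

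The 4 h response to 1 µg/ml LTA was larger in dHL-60 than in uHL-60 for NF-κB, cytokine and chemokine genes. In the difference of responses 17 of 23 were higher and 0 lower (19 and 0 over the list alone) in the NF-κB list. There 7 of 23 were higher and 0 lower (8 and 0 over the list alone) among cytokines and 4 of 18 were higher and 0 lower (7 and 0 over the list alone) among chemokines. The 3 set tests gave adjusted p = 8.89e-16 to 2.47e-11, and 0.196 to 0.243 with an estimated correlation. SERPINB9 differed by 7.45 ± 0.70, NFKB1 by 2.49 ± 0.23, IL1B by 4.85 ± 0.62, CCL5 by 3.53 ± 0.28, IFIH1 by 1.65 ± 0.26 and STARD4 by 3.13 ± 0.48. FAM72D differed by 9.57 ± 1.06 and CCL4L2 by 6.81 ± 1.80, both with near-identical copies and a group of at most 3 counts, so these values depend on the prior count, and CCL4L2 was not called by limma-voom. CD1D differed by -4.74 ± 0.44, the immunoglobulin-like receptor LILRA1 by -4.11 ± 0.48, the claudin CLDN9 by -3.96 ± 0.87, CXCR2 by -2.58 ± 0.36 and KIT by -2.62 ± 0.31, and the adjusted p of these 13 was at most 0.027. Cholesterol genes had 4 higher and 0 lower of 20 (5 and 0 over the list alone), immediate early genes 10 higher and 0 lower of 27 (15 and 1 over the list alone) and promyelocyte genes 0 higher and 4 lower of 24 (0 and 5 over the list alone). These 3 gave adjusted p = 3.99e-07 to 0.0309, and 0.254 to 0.563 with an estimated correlation. Another 5 lists passed, with members higher and lower (over the list alone) numbering 2 and 0 of 31 (2 and 0) in the cell cycle, 12 and 1 of 29 (16 and 2) in apoptosis, 4 and 0 of 21 (7 and 0) in the unfolded protein response, 0 and 2 of 20 (0 and 1) in ribosome biogenesis and 0 and 2 of 7 (0 and 2) in markers of red cells and platelets. These 5 gave adjusted p = 0.000116 to 0.0243, and 0.196 to 0.503 with an estimated correlation. Mature neutrophil genes had 2 and 2 of 25 (3 and 2) and interferon genes 2 and 0 of 26 (2 and 2) and did not pass (adjusted p = 0.873 to 0.879). TLR2 differed by 2.64 ± 0.29 and MYD88 by 1.21 ± 0.26 (adjusted p = 0.000147 and 0.00879). TLR1 at 0.38 ± 0.40, TLR6 at -0.62 ± 0.44, CD14 at -0.65 ± 0.48, ITGAM at -0.55 ± 0.37 and MPO at -0.19 ± 0.38 were not called (adjusted p = 0.43 to 0.828). The test called 1266 of 12713 genes, 711 higher and 555 lower, against 567 and 793 with upper-quartile scaling, which moved the median of all genes by -0.13. It called over the kept symbols 1221 of 11402, of which 1167 were also called over all symbols. Each uHL-60 group is 1 library and was assumed to vary like dHL-60 replicates.

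At 24 h the responses of dHL-60 and uHL-60 to 1 µg/ml LTA differed in fewer genes than at 4 h. In the NF-κB list 3 of 23 were higher and 0 lower (15 and 0 over the list alone), and among chemokines 1 of 18 were higher and 0 lower (2 and 0 over the list alone). Among mature neutrophil genes 6 of 25 were higher and 0 lower (8 and 0 over the list alone), and among promyelocyte genes 0 of 24 were higher and 2 lower (1 and 14 over the list alone). Set tests of these 4 gave adjusted p = 2.94e-12 to 3.32e-05, and 0.196 to 0.255 with an estimated correlation. Another 12 lists passed, with members higher and lower (over the list alone) numbering 1 and 0 of 23 (2 and 0) in cytokines, 2 and 0 of 26 (5 and 0) in interferon genes, 2 and 0 of 22 (7 and 0) in Toll-like receptor signalling and 3 and 0 of 27 (9 and 0) in immediate early genes. There were 2 and 0 of 14 (3 and 1) in macrophage markers, 2 and 0 of 7 (2 and 0) in lymphocyte markers, 2 and 0 of 8 (3 and 0) in the NADPH oxidase and 3 and 0 of 31 (11 and 0) in the cell cycle. There were 3 and 0 of 26 (13 and 0) in glycolysis, 3 and 0 of 15 (4 and 0) in antioxidant genes, 0 and 0 of 20 (0 and 0) in cholesterol genes and 0 and 0 of 20 (0 and 0) in ribosome biogenesis. Cholesterol genes passed as higher and ribosome biogenesis as lower. These 12 gave adjusted p = 2.51e-10 to 0.0405, and 0.196 to 0.563 with an estimated correlation. JAK3 differed by 7.48 ± 0.87, CES1 by 5.27 ± 0.63, CCL5 by 3.28 ± 0.28, the calprotectin subunit S100A9 by 2.55 ± 0.33, the death ligand TNFSF10 by 1.96 ± 0.39, the urokinase receptor PLAUR by 1.81 ± 0.36 and PARP9 by 1.56 ± 0.30. The transcription factor POU2F2 differed by 7.29 ± 1.46, a value that depends on the prior count because 1 group has at most 3 counts. PLD4 differed by -2.94 ± 0.49, SPON2 by -2.78 ± 0.65, SDK2 by -2.56 ± 0.45 and KIT by -1.99 ± 0.30, and the adjusted p of these 12 was at most 0.0449. TLR2 differed by 1.24 ± 0.29, TLR1 by 1.66 ± 0.38 and ITGAM by 1.60 ± 0.32 (adjusted p of at most 0.0449), while TLR6 at 1.42 ± 0.42, CD14 at 3.16 ± 0.82, MYD88 at 0.89 ± 0.26 and MPO at -1.07 ± 0.38 were not called (adjusted p = 0.0706 to 0.19). The test called 227 genes, 197 higher and 30 lower, against 484 and 153 with no filter, 310 and 71 with DESeq2 and 131 in all with limma-voom. Over the kept symbols it called 206, of which 204 were also called over all symbols. Over all symbols it called 75 and 7 without treated replicate 1, 98 and 10 without control replicate 1 and 95 and 12 without control replicate 2 of dHL-60. The calls of POU2F2 (7.08), SPON2 (-2.81), PARP9 (1.59) and TLR1 (1.79) ended without control replicate 1. Those of SPON2 (-2.76), PLAUR (1.66), TNFSF10 (1.89), PARP9 (1.53), TLR2 (1.05) and TLR1 (1.55) ended without control replicate 2. Those of SPON2 (-2.51), PLAUR (1.74), TNFSF10 (1.90), PARP9 (1.47), TLR2 (1.05), TLR1 (1.48) and ITGAM (1.52) ended without treated replicate 1.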

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

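The tests on the 4 h controls and the LTA programme, on marker lists and on read numbers were chosen after the result was seen. Each difference here between 2 responses passed a test of its own. For 1 µg/ml LTA in dHL-60 the response differed between 24 and 4 h in 2461 genes, but in 1614 without the 24 h control replicate 1. Responses of DAB2 (5.34), FCGR2B (5.33), YPEL4 (5.32), CXCL16 (1.52), PARP9 (2.39), ITGAM (1.95), TLR1 (1.52), TLR6 (2.03) and CD14 (1.52) were higher at 24 h on the log2 scale. Those of MIR155HG (-7.69), CCL20 (-5.04), NMNAT3 (-3.99), NFKB1 (-1.75), IL1B (-2.41), CTSG (-1.61), STARD4 (-2.25), TLR2 (-1.29) and MPO (-1.02) were lower. FCGR2B was not called without the 4 h control replicate 2 (3.42) and stood at 9.65 without the 4 h treated replicate 2, and CCL20 was not called without the 24 h control replicate 2 (-4.30). MPO was not called without control replicate 2 at 4 h (-0.82) or 24 h (-0.81), treated replicate 1 or 2 at 4 h (-0.98 and -1.08) or treated replicate 1 at 24 h (-0.79).

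For 10 µg/ml LTA the difference passed in 4001 genes, but in 2660 without the 4 h treated replicate 1. Higher at 24 h were the responses of HBB (6.94), DAB2 (6.78), LILRB1 (6.41), EBI3 (2.55), CXCL16 (2.58), PARP9 (2.42), C5AR1 (3.62), TLR1 (1.51), TLR6 (2.32), CD14 (2.77) and ITGAM (2.20). Lower were those of MIR155HG (-6.64), ELOVL7 (-5.64), IL12B (-4.29), NFKB1 (-1.49), CTSG (-1.89), STARD4 (-2.12), TLR2 (-0.68) and MPO (-1.45). HBB, DAB2 and IL12B rest on groups of at most 3 counts, so their values depend on the prior count, and DAB2 stood at 10.74 without the 4 h treated replicate 2. IL12B was not called without control replicate 1 at 4 h (-4.33) or 24 h (-1.51) or treated replicate 1 at 4 h (-4.23) or 24 h (-4.08), nor TLR2 without those 4 libraries (-0.66, -0.46, -0.64 and -0.71) or the 24 h treated replicate 2 (-0.71).

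Responses of dHL-60 and uHL-60 to 1 µg/ml LTA at 4 h differed in 1266 genes (1221 over kept symbols). Higher in dHL-60 were those of FAM72D (9.57), SERPINB9 (7.45), CCL4L2 (6.81), IL1B (4.85), CCL5 (3.53), STARD4 (3.13), TLR2 (2.64), NFKB1 (2.49), IFIH1 (1.65) and MYD88 (1.21). Lower were those of CD1D (-4.74), LILRA1 (-4.11), CLDN9 (-3.96), KIT (-2.62) and CXCR2 (-2.58). FAM72D and CCL4L2 have near-identical copies and a group of at most 3 counts, so their values depend on the prior count.

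At 24 h they differed in 227 genes (206 over kept symbols), but in fewer without dHL-60 treated replicate 1 or control replicate 1 or 2. Higher in dHL-60 were the responses of JAK3 (7.48), POU2F2 (7.29), CES1 (5.27), CCL5 (3.28), S100A9 (2.55), TNFSF10 (1.96), PLAUR (1.81), TLR1 (1.66), ITGAM (1.60), PARP9 (1.56) and TLR2 (1.24). Lower were those of PLD4 (-2.94), SPON2 (-2.78), SDK2 (-2.56) and KIT (-1.99). POU2F2 has a group of at most 3 counts, so its value depends on the prior count. POU2F2 (7.08), SPON2 (-2.81), PARP9 (1.59) and TLR1 (1.79) were not called without control replicate 1, and SPON2 (-2.76), PLAUR (1.66), TNFSF10 (1.89), PARP9 (1.53), TLR2 (1.05) and TLR1 (1.55) without control replicate 2. Without treated replicate 1 SPON2 (-2.51), PLAUR (1.74), TNFSF10 (1.90), PARP9 (1.47), TLR2 (1.05), TLR1 (1.48) and ITGAM (1.52) were not called.

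The responses at 24 and 4 h rest on different controls, and 14 of 18 chemokines were lower in untreated dHL-60 at 24 h than at 4 h. A single control library does not account for this, since at least 13 chemokines were called lower whichever of the 4 control libraries was left out. A return toward the undifferentiated state stays open, as the marker lists point both ways. At 24 h 22 of 26 mature neutrophil genes were called lower and 20 of 24 ribosome biogenesis genes higher, which is toward uHL-60. Of 33 cell cycle genes, which are higher in uHL-60, 11 were called lower and 4 higher, and that list did not pass (adjusted p = 0.269). Part of the LTA programme may have been on in the 4 h controls: across genes, which are not independent replicates, the change in controls from 4 to 24 h correlated at r = -0.504 with the change from 1 to 10 µg/ml at 24 h, and these comparisons share no library. What would have turned it on was not tested, and time in culture, which the design names, stays open as well.

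In uHL-60 at 4 h, 2 of 8890 genes with at least 5 CPM differed by at least 2-fold with LTA. Over 2751 kept genes called in dHL-60 and with at least 10 CPM in uHL-60, the slope of the uHL-60 log2 ratio on the dHL-60 log2 fold change was -0.0149 (-0.0192 to -0.0107, 95% over 1000 resamples of genes), which argues against the same response at a smaller size in these genes. Too few reads stay open for part of the response. Of 985 kept genes called and at least 2-fold higher in dHL-60, at any level in uHL-60, 62.8% had an upper interval bound under 1 log2 in uHL-60. CSF3 and IL12B had 0 counts in both uHL-60 libraries at 4 h. The 392 with at least 10 CPM had a median of -0.030 log2 in uHL-60 against 1.41 in dHL-60. The lower receptor levels of uHL-60 stay open as untested, with 0.648 against 509 CPM of CD14 and 18.3 against 199 CPM of TLR2 in the 4 h controls. With 1 library per group, a stimulus that did not reach that uHL-60 culture could not be separated from a lack of response.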

How the results depend on the processing

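Keeping part of the symbols, realigning the uHL-60 columns and fitting LTA over both times in uHL-60 were chosen only after the data were seen. Called genes at a minimum change of 2-fold numbered 2063 (1 µg/ml LTA, 4 h), 2245 (10 µg/ml, 4 h), 1049 (1 µg/ml, 24 h), 2128 (10 µg/ml, 24 h), 203 (dose, 24 h), 1992 (controls over time), 1559 and 2478 (24 h against 4 h response, 1 and 10 µg/ml), since that threshold is stricter by construction. For the dose comparison at 4 h, 1 gene in the report, the count was 22 with no filter, 0 with the stricter filter (edgeR, 166 at an unadjusted p under 0.05), under which HBB was not tested, 2 with DESeq2, 2 with all 16 libraries and 2 with only the 6 libraries of the time point. For dose at 24 h (453 genes) it was 1354 with no filter, 753 with DESeq2 and 705 with those 6 libraries. For the 24 h responses of dHL-60 against uHL-60 (227 genes) it was 637 with no filter, 381 with DESeq2, 131 with limma-voom and 347 with the replicate block. Apart from the minimum change and HBB, the cause was not tested. With 1 library left out, counts ran from 3181 to 4355 for 10 µg/ml at 4 h, 1139 to 1758 for 1 µg/ml at 24 h, 1 to 2 and 49 to 662 for dose at 4 and 24 h, 3138 to 4226 for controls over time, 1614 to 2270 and 2660 to 4051 for the responses over time at 1 and 10 µg/ml, and 82 to 215 for the 24 h responses of dHL-60 against uHL-60. Beyond 1.5 times moved 10 µg/ml at 4 h without its replicate 1 (3181), 1 µg/ml at 24 h without treated replicate 1 (1139) or control replicates 1 and 2 (1451 and 1593), controls over time without 24 h replicate 1 (3138), and the responses over time without the 24 h control replicate 1 (1614, 1 µg/ml) and the 4 h treated replicate 1 (2660, 10 µg/ml). So did dose at 4 h without 10 µg/ml replicate 2 (2), dose at 24 h without 1 µg/ml replicates 1 and 2 (191 and 49) or 10 µg/ml replicate 1 (73), and the 24 h responses of dHL-60 against uHL-60 without treated replicate 1 (82) or control replicates 1 and 2 (108 and 107). An arm left with 1 library was assumed to vary like the other groups, and leaving out a lone uHL-60 library of a difference of responses gives no value. With an estimated correlation 0 of the 155 list calls were made, with fry 143. In uHL-60 at 4 h, MPO went from -0.010 to 0.011 with library size only, and over kept symbols 1 gene at 4 h and 2 genes at 24 h differed by 2-fold, against 2 and 7 over all symbols, a larger set by construction. Counts within 1.5 times of those in the report numbered 16 of 16 with DESeq2 size factors, 13 of 13 with upper-quartile scaling, 10 of 13 with no filter, 12 of 13 with the stricter filter, 10 of 13 with DESeq2, 12 of 13 with limma-voom and 3 of 3 with realigned columns. Of 260 calls of genes taken by the naming rule none reversed in these fits, and 17 ended at a minimum of 2-fold, 8 with limma-voom, 4 with upper-quartile scaling, 2 of 138 with the 6 libraries, 1 each with DESeq2, DESeq2 size factors, no filter and all 16 libraries (of 203), and 27 without at least 1 library. Replicate numbers are shared between groups by number only: deviations from group means correlated across 15 group pairs at r = -0.204 to 0.383 (median 0.0882, 5 over 0.1, 3 under -0.1). A fit with the replicate block left 15 of 16 counts within 1.5 times and ended 0 of those 260 calls. The additive fit of LTA in uHL-60 called 23 genes, and 9 over the kept symbols. Depth limits genes with few counts: a gene with 0 counts in a group gives only a bound at 3 counts.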

Other observations

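Both tests on the gene table, and the gene HBB, were chosen only after the result was seen.

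The adult globin gene HBB, on chromosome 11, 5225464 to 5227071 of GRCh38, went in and out of detection across the dHL-60 groups. At 4 h it stood at 33.5 ± 2.14 CPM in untreated cells, 0.324 ± 0.235 CPM with 1 µg/ml LTA and 22 ± 1.84 CPM with 10 µg/ml (mean ± SD, n = 2). At 24 h it had 0 counts in untreated cells, 1.18 ± 0.207 CPM with 1 µg/ml and 0.782 ± 0.273 CPM with 10 µg/ml. The order of the 4 h groups did not follow the dose. No explanation was tested.

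LTA libraries of uHL-60 differed from their controls by less than dHL-60 replicates differed from each other, at these depths. The chi-square per degree of freedom was 2.27 at 4 h and 5.77 at 24 h, against 10.9 to 19.96 for the 6 pairs of dHL-60 replicates and 8.51 for the uHL-60 controls at 24 against 4 h. Intervals for counting error excluded 0 for 16.3% of uHL-60 genes at 4 h and 33.8% at 24 h, and across 8928 genes, which are not independent replicates, the 4 and 24 h log2 ratios correlated at r = -0.0726.

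In part of the gene table the uHL-60 columns lay far from the dHL-60 columns. For the 1343 symbols that a plain character sort moves, mean log2 CPM of dHL-60 and uHL-60 correlated across genes at r = 0.251 as deposited and 0.905 after the uHL-60 columns were put in that order, against 0.941 for symbols in the same position. Of those, 372 were tested between untreated dHL-60 and uHL-60 and 356 called. A second set, 220 genes with over 50% of exon bases shared with another gene on the same strand, had a median difference of -3.56 log2 (dHL-60 minus uHL-60), against -0.072 for 8447 genes that share none. This is consistent with uHL-60 columns that were joined in another row order and counted with another rule for reads in shared exons, neither of which the sources used here state, and a biological explanation was not tested.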
